A study of Rattus norvegicus with 4 samples.

How the data were processed

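Small RNA of extracellular vesicles was measured on 4 single-colour (Cy3) Agilent rat miRNA arrays, release 21 of the miRNA catalogue. Per the labels' protocols, knee OA was induced in male rats by destabilising the medial meniscus and cutting the anterior cruciate ligament, and marrow was taken 8 weeks after surgery. Cells positive for CD45 and CD11b were sorted and grown with 20 ng/mL M-CSF to day 7 (M0). M1 cells had 100 ng/mL LPS and 20 ng/mL interferon-γ for 48 hours, then 5 mM ATP for 60 minutes. Arrays were labelled from 0.2 µg RNA; the labelling text in the labels describes a linear amplification of cRNA, and whether that kit was used on these miRNA arrays is unclear. The sample titles give M0 or M1 and the replicate number, but not the surgery.

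The deposited scanner files hold spot intensity from Agilent Feature Extraction 10.7.1.1 (per the file headers and the submitters' processing notes). Per the file headers, the processed intensity had its background subtracted with spatial detrending, so it can be below 0, and outlier spots were marked; no scaling between arrays was applied. The mean and local background intensities in the deposited files are raw. The files also hold flags of 0 or 1, among them whether a spot is well above background. A deposited series table of log2 values, made by the authors, has its floor at -3.32, the log2 of 0.1, and the median of every column lies there. Its values followed each array's own summed processed signal (Spearman rho 0.870, 0.857, 0.984 and 0.987 for M0_sham replicates 1 and 2 and M1_OA replicates 1 and 2, across miRNAs above the table's floor, which are not independent replicates). The highest correlation of each column with another array's signal was lower (0.733, 0.782, 0.923 and 0.894). With each array's own total gene signal, over miRNAs detected there, rho was 0.422, 0.508, 0.650 and 0.520. The scale is log2 and the columns follow the arrays of their labels; the normalization between arrays stays unknown. 8 entries of that table are not miRNAs and were left out.

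For each array, the processed signals of a probe's unmarked spots were averaged on the linear scale and the probes of a miRNA were summed (1806 probes and 12128 spots for 758 miRNAs). A miRNA was well above background on an array where a share above 0.5 of the spots of at least 1 of its probes carried that flag. As most miRNAs were not detected, each array was scaled to the 75th percentile over the 11 miRNAs well above background on all 4 arrays. Values under 7.90, the lowest scaled signal of a detected miRNA, were set to that floor before log2 was taken. The 41 miRNAs well above background on both arrays of at least 1 group were tested with limma 3.58.1 (lmFit and default eBayes, two-sided, BH over the 41) in R 4.3.3. The threshold was an adjusted p of 0.05. Lower bounds of fold used means of log2 values with the array's detection limit in place of dimmer signals. No spot was saturated (0 in all). Lists with at least 3 tested members were tested with camera (correlation 0.01). Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

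The arrays' lowest signals well above background were 7.78 and 26.7 on M0_sham replicates 1 and 2 and 16.9 and 14.6 on M1_OA replicates 1 and 2, and signals below these are not resolved. Replicates correlated across the tested miRNAs with r = 0.973 in M0_sham and 0.968 in M1_OA, against 0.62 to 0.71 between groups. miRNAs are not independent replicates. These are floored values: 16 tested miRNAs share the floor on both M0_sham arrays, and 24 were admitted through M1_OA only. The gap between these correlations is therefore partly built in by floor and filter. In 300 simulated sets of 41 miRNAs with 2 arrays a group, the same limma fit called 53.8% of miRNAs changed by a log2 of 1, 80.3% by 2 and 88.2% by 3. Of the calls, 5.66% were false, and 8.67% of sets without any change had a call. The sets were drawn as log2 values, without scaling, floor or detection filter. These rates therefore do not cover miRNAs set to the floor or admitted through 1 group.

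The comparison, its alternatives, the lists (LPS and NF-κB, M2, myeloid, miR-17-92, let-7, miR-23/24/27, miR-29, miR-30, miR-221 and miR-222, cartilage and OA, erythroid, liver and serum, lymphocyte, stromal, muscle, epithelial, endothelial and neuronal) and the rule for naming miRNAs were fixed before the data were examined. The rule takes up to 12 miRNAs in each direction by fold among those that passed and were measured in both groups, filled up to 8 with miRNAs whose arrays do not overlap. It adds up to 6 in each direction measured in 1 group only, up to 4 of each list by p, and miR-155-5p, miR-146a-5p, miR-223-3p, miR-142-3p, miR-451-5p and miR-122-5p. Alternatives covered the background correction, scaling, filter, detection call, summary of probes, variance prior, replicate numbers, each replicate left out, the threshold and an unmoderated fit. The other background correction was normexp with an offset of 50. Scaling to the labelling spike-ins, a higher floor and a percentile without CTCC-holding probes were added after the data were seen.

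A planned test of the sequence motifs AAUGC and GGAG in mature miRNAs was not run, because the probes cover only part of each mature sequence; full mature sequences were not analysed here. All 4 arrays share 1 slide and each of the 2 scan sessions holds 1 group, so no fit with slide or session as a term could be had. The RefSeq gene table used for neighbouring genes is on GRCr8, another build than the files' rn4, so no position was taken from it.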

Results

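Extracellular vesicles, the membrane-bound particles that cells release, were collected from cultured rat bone-marrow-derived macrophages, and their RNA was hybridised to single-colour microarrays carrying probes for 758 mature rat miRNAs. The M0_sham group (n = 2 arrays) holds vesicles of resting (M0) macrophages grown from the marrow of sham-operated rats. The M1_OA group (n = 2 arrays) holds vesicles of macrophages from rats with surgically induced knee osteoarthritis (OA), polarised to the inflammatory M1 state with lipopolysaccharide (LPS) and interferon-γ and then given ATP. Surgery, polarisation and ATP change together, so the arrays give 1 contrast. On M0_sham replicates 1 and 2, 23 and 13 miRNAs were well above background, against 42 and 45 on M1_OA replicates 1 and 2. Of the 758 miRNAs, 703 were well above background on no array and 11 on all 4. The labels do not say that the replicates came from separate animals or cultures, so p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision. Each of the 2 scan sessions held arrays of 1 group, so scan session and group cannot be told apart. miRNA names are given without the prefix rno- that the files use.

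The contrast addresses which miRNAs the vesicles of inflammatory macrophages from OA rats carry in comparison with those of resting macrophages from sham rats. miR-21-5p, which NF-κB and STAT3 signalling induce, was well above background on both M1_OA arrays, with signals of 387 and 320 (background-subtracted, arbitrary units, before scaling), and not well above background on either M0_sham array (3.10 and 0.122). miR-23a-3p had signals of 427 and 307 in M1_OA vesicles and was likewise not well above background in M0_sham vesicles (4.77 and 4.42). The LPS-responsive miR-146a-5p (191 and 107) and miR-155-5p (72.4 and 60.3) and the p53-induced miR-34a-5p (122 and 92.1) were also well above background on both M1_OA arrays and on neither M0_sham array. In all, 24 miRNAs were well above background in M1_OA vesicles only. Of these, 19 passed as higher, 14 with a scaled lower bound of fold over 1 and 5 with one under 1. In M0_sham vesicles only it was 1, miR-296-5p (23.4 and 26.7), whose M1_OA signals (22.1 and 15.6) were not well above background by the arrays' spot flags, although above the lowest signals of miRNAs that were (16.9 and 14.6).

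**Figure D1:**
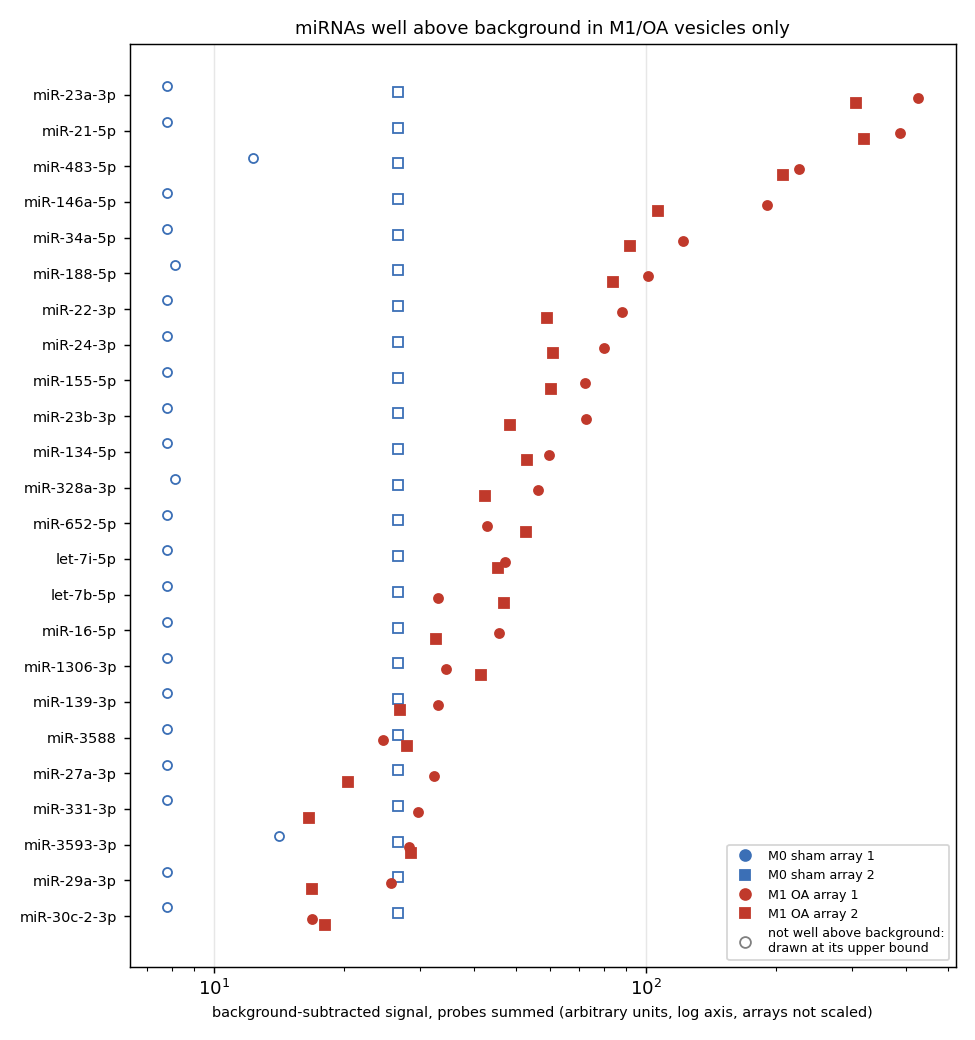
Each line is one of the 24 miRNAs well above background on both M1_OA arrays and on neither M0_sham array; the x axis is the background-subtracted signal in arbitrary units on a log axis, without scaling, with 1 point per array. Open points were not well above background and stand at their upper bound; the filled M1_OA points of miR-23a-3p, at 427 and 307, lie farther right than both of its M0_sham bounds.

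For a miRNA measured in M1_OA only, the fold is a lower bound. It sets the M1_OA mean against 1 value per M0_sham array: the higher of the lowest signal well above background there and the miRNA's own signal. A bound under 1 means that the M1_OA mean lay below the mean of these M0_sham values. A call with such a bound rests on the floor and does not show a rise. For miRNAs higher in M1_OA, the p-value beside a bound is limma's for the difference of floored values, and the bound itself was not tested. With scaling that difference was a log2 of 4.55 for miR-23a-3p. The scaled floor, a log2 of 2.98, lies below the detection limits of both M0_sham arrays (3.99 and 5.35). miR-23a-3p was at least 8.08-fold higher in M1_OA vesicles after scaling to the 75th percentile (limma, Benjamini-Hochberg (BH) adjusted p = 0.00102) and at least 25.1-fold higher without scaling (limma, BH-adjusted p = 1.39e-04). miR-21-5p was at least 7.85-fold higher with scaling (limma, BH-adjusted p = 0.00102) and 24.4-fold without (limma, BH-adjusted p = 1.39e-04). For 16 of the 24 miRNAs, among them miR-21-5p, miR-34a-5p, miR-146a-5p, miR-155-5p, miR-24-3p, miR-23b-3p, miR-16-5p, miR-27a-3p, miR-29a-3p and let-7i-5p, both M0_sham values were set to the floor, so their p-values hold no spread of the M0_sham arrays and rest on the M1_OA spread and limma's shared variance. miR-483-5p, encoded in an intron of Igf2, was at least 3.84-fold higher (limma, BH-adjusted p = 0.0040). Its probe holds the sequence CTCC, a feature that went with higher M1_OA signal across the array. The call ended on the authors' value table, where the log2 difference was 2.57 against 2.20 (limma, BH-adjusted p = 0.102). miR-146a-5p was at least 3.18-fold higher (limma, BH-adjusted p = 0.00104), and miR-34a-5p at least 2.36-fold (limma, BH-adjusted p = 0.00104). miR-188-5p, whose probe also holds CTCC, was at least 2.01-fold higher (limma, BH-adjusted p = 0.0040). miR-296-5p was 4.18-fold lower in M1_OA vesicles (limma, BH-adjusted p = 0.00207). This is an estimate and not a bound, as both its M1_OA signals lay above the lowest signals well above background. Without scaling it was 1.34-fold lower and no longer passed (limma, BH-adjusted p = 0.200). It also did not pass without M1_OA replicate 1 (log2 difference -2.04). Without M0_sham replicate 2, 8 miRNAs in place of 1 were well above background in M0_sham vesicles only.

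Of the 18 miRNAs on the array that were listed as LPS- and NF-κB-responsive, 3 were tested, and all 3, miR-21-5p, miR-146a-5p and miR-155-5p, rose in M1_OA vesicles, also when adjusted over the list alone. All 3 entered the test only through their M1_OA signal, so a rise was largely fixed by the filter. The same holds for every tested member of the cartilage and OA, miR-23/24/27, M2, let-7, miR-29, erythroid, liver and serum, and lymphocyte lists below. Of the 24 miRNAs that entered this way, 19 passed as higher, and of all 41 tested, 22 did. miR-155-5p, which targets Socs1 and Inpp5d, was at least 1.47-fold higher with scaling (limma, BH-adjusted p = 0.00207) and at least 4.58-fold without (limma, BH-adjusted p = 2.89e-04). miR-146a-5p, which targets Traf6 and Irak1 in the Toll-like receptor pathway, is also on the list of cartilage and OA miRNAs, where it and miR-34a-5p were the 2 tested of the 15 listed and both rose, also adjusted over the list alone. The remaining members of the LPS list, among them miR-146b-5p, miR-147 and miR-132-3p, were not well above background, except miR-212-3p on 1 array.

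Of the 7 arms listed for the miR-23/24/27 clusters, which leave out further arms on the array that were not well above background, 4 were tested, and all 4 passed as higher in M1_OA vesicles, also when adjusted over the list alone. Their genes neighbour each other in 2 places in the GRCr8 annotation, Mir23a with Mir27a and Mir24-2, and Mir23b with Mir27b and Mir24-1. Besides miR-23a-3p, miR-24-3p was at least 1.56-fold higher (limma, BH-adjusted p = 0.0012), and miR-23b-3p at least 1.32-fold (limma, BH-adjusted p = 0.0012). For miR-27a-3p the scaled bound was under 1, so with scaling its call rests on the floor and does not show a rise. Without scaling miR-27a-3p was at least 1.78-fold higher (limma, BH-adjusted p = 0.0047, against 0.00903 with scaling). Its log2 difference was 0.88, and its call ended with quantile normalization (1.00; limma, BH-adjusted p = 0.0504), in the authors' table (0.71; limma, BH-adjusted p = 0.251), with the percentile over probes without CTCC (1.27; limma, BH-adjusted p = 0.157), without M0_sham replicate 1 (0.81; limma, BH-adjusted p = 0.0867) and without M0_sham replicate 2 (0.75; limma, BH-adjusted p = 0.153). The probes of miR-23a-3p and miR-23b-3p are closely alike (GGAAATCCCTGGCAATGT and GGTAATCCCTGGCAATGT), and binding of each miRNA to the other's probe was not tested. miR-23a-3p, miR-24-3p and miR-27a-3p were also the 3 tested of the 10 miRNAs listed for alternative (M2) activation, and all 3 passed as higher, also adjusted over the list alone. The other 7 of that list, miR-124-3p and miR-511-3p among them, were not well above background on any array. As the 3 are the same miRNAs as in the cluster list, their rise is no separate result and does not show M2 activation.

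Among the 12 miRNAs listed as myeloid, 3 were tested and 2 passed as higher, miR-21-5p and miR-16-5p, also when adjusted over the list alone. For miR-16-5p the scaled bound was under 1 (limma, BH-adjusted p = 0.00273), and the bound without scaling was at least 2.68-fold (limma, BH-adjusted p = 9.60e-04). miR-223-3p, the abundant miRNA of granulocytes and monocytes, did not pass, with a log2 difference of -0.25 ± 0.37 (SE; limma, BH-adjusted p = 0.576), and its direction turned without scaling (1.38; limma, BH-adjusted p = 0.00932). miR-142-3p, a miRNA of blood cells in general, was not well above background on any array. Of the 9 arms listed for the let-7 family, miR-98-5p included, 2 were tested: let-7i-5p rose, at least 1.03-fold with scaling (limma, BH-adjusted p = 0.00788) and 3.21-fold without (limma, BH-adjusted p = 3.10e-04), and let-7b-5p did not pass (log2 difference 0.50; limma, BH-adjusted p = 0.447), but did without scaling (1.97; limma, BH-adjusted p = 0.00521). miR-29a-3p, the 1 tested of the 4 miR-29 arms listed, passed as higher with a scaled bound under 1 (limma, BH-adjusted p = 0.0252) and was at least 1.44-fold higher without scaling (limma, BH-adjusted p = 0.00756). The call with scaling ended with the percentile over probes without CTCC (log2 difference 0.97 against 0.58; limma, BH-adjusted p = 0.262), without M0_sham replicate 1 (0.51; limma, BH-adjusted p = 0.165) and without M0_sham replicate 2 (0.45; limma, BH-adjusted p = 0.329). miR-92a-3p, the 1 tested of 17 listed for the miR-17-92 and paralogous clusters, did not pass (log2 difference -0.69 ± 0.39 SE; limma, BH-adjusted p = 0.230), and its direction turned without scaling (0.88; limma, BH-adjusted p = 0.0314). Adjusting over each of these 3 lists alone gave the same counts. For the miR-29 and miR-17-92 lists, with 1 tested member each, that is the unadjusted p.

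The lists for other cell types and for blood gave few members. Of the 12 stromal, 7 epithelial, 2 endothelial and 8 neuronal miRNAs listed, 0 were well above background on any array. The muscle list and the miR-30 list each had 1 member well above background, on 1 array; miR-30c-2-3p, an arm outside that list named after its values were seen, was well above background on both M1_OA arrays (16.9 and 18.0) and did not pass (limma, BH-adjusted p = 0.395). It passed as higher without scaling (log2 difference 1.17; limma, BH-adjusted p = 0.00521), and its probe holds CTCC. On both lists 0 were tested, and the cluster of miR-221 and miR-222 had 0. The red cell marker miR-451-5p and the liver marker miR-122-5p were not well above background on any array. miR-16-5p was the 1 tested miRNA of the 6 erythroid ones, miR-483-5p of the 6 liver and serum ones and miR-155-5p of the 7 lymphocyte ones. Each passed as higher, having entered the test through its M1_OA signal only. With 1 tested member, adjusting over the list alone leaves the unadjusted p and adds nothing.

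Of the 11 miRNAs well above background on all 4 arrays, 2 rose and 3 fell in M1_OA vesicles after scaling. miR-1896 rose by a log2 fold change of 2.53 ± 0.30 (SE, n = 2 and 2; limma, BH-adjusted p = 0.0063), from signals of 47.5 and 96.3 to 1291 and 1151 before scaling. miR-6216 rose by 1.28 ± 0.27 (limma, BH-adjusted p = 0.0272). miR-466b-5p fell, with a log2 fold change of -2.11 ± 0.54 (limma, BH-adjusted p = 0.0396), as did miR-1249 (-1.60 ± 0.18; limma, BH-adjusted p = 0.00527) and miR-3584-5p (-1.15 ± 0.24; limma, BH-adjusted p = 0.0261). miR-1224 (0.59 ± 0.31), miR-32-3p (-1.30 ± 0.58), miR-423-5p (-0.96 ± 0.54) and miR-672-5p (-0.95 ± 0.60) did not pass (limma, BH-adjusted p from 0.157 to 0.266). The probes of miR-1896, miR-6216, miR-1224 and miR-3584-5p hold CTCC.

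These values rest on the scaling. Without it, none of the 3 that fell passed: the log2 difference was -0.47 for miR-466b-5p, 0.035 for miR-1249 and 0.49 for miR-3584-5p (limma, BH-adjusted p = 0.216, 0.890 and 0.163). When scaled to the labelling spike-ins instead, miR-1249 and miR-3584-5p passed as higher (0.56 and 1.01; limma, BH-adjusted p = 0.0122 and 0.00827), and miR-466b-5p did not pass (0.048; limma, BH-adjusted p = 0.908). In the unscaled fit, miR-32-3p, miR-423-5p and miR-672-5p lay at 0.33, 0.68 and 0.69, none passing, and miR-1224 passed as higher at 2.22 (limma, BH-adjusted p = 0.00469), while the authors' table gave it -0.062. miR-6216 kept its direction but not its call in 11 of 20 alternatives, quantile normalization and the authors' table among them (0.57 and 0.65; limma, BH-adjusted p = 0.0569 and 0.114; range over its alternatives 2.89e-04 to 0.418), and miR-466b-5p in 10 of 20, the authors' table among them (-2.37; limma, BH-adjusted p = 0.0507; up to 0.908 over its alternatives). With the replicates left out in turn, the log2 difference of miR-1896 was 2.73 without M1_OA replicate 1 and 2.34 without M1_OA replicate 2, where it did not pass (limma, BH-adjusted p = 0.116 and 0.126). miR-6216, with the same direction, did not pass without either array (limma, BH-adjusted p = 0.178 and 0.247). Without M1_OA replicate 1, miR-466b-5p, miR-1249 and miR-3584-5p did not pass, at -1.46, -1.45 and -0.88 (limma, BH-adjusted p = 0.134, 0.0501 and 0.0667). miR-466b-5p was also lost without M1_OA replicate 2 or M0_sham replicate 1 (-2.76 and -1.71; limma, BH-adjusted p = 0.0626 and 0.161), and miR-3584-5p without M0_sham replicate 1 or 2 (both in the same direction; limma, BH-adjusted p = 0.0867 and 0.0741). Of those that did not pass, miR-423-5p lay at -0.016 without M0_sham replicate 2 and passed as lower, at -1.43, without M0_sham replicate 1 (limma, BH-adjusted p = 0.0225). miR-1224 passed as higher without M0_sham replicate 2 (1.12; limma, BH-adjusted p = 0.0330), and miR-32-3p as lower without M1_OA replicate 2 (-2.04; limma, BH-adjusted p = 0.0324) and with quantile normalization (-1.86; limma, BH-adjusted p = 0.0451; up to 0.911 over its alternatives). With normexp miR-32-3p, miR-423-5p and miR-672-5p all passed as lower (-0.99, -1.04 and -0.92; limma, BH-adjusted p = 0.00102, 8.16e-04 and 0.00152), and miR-1224 passed as higher (0.99; limma, BH-adjusted p = 0.00102).

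**Figure D2:**
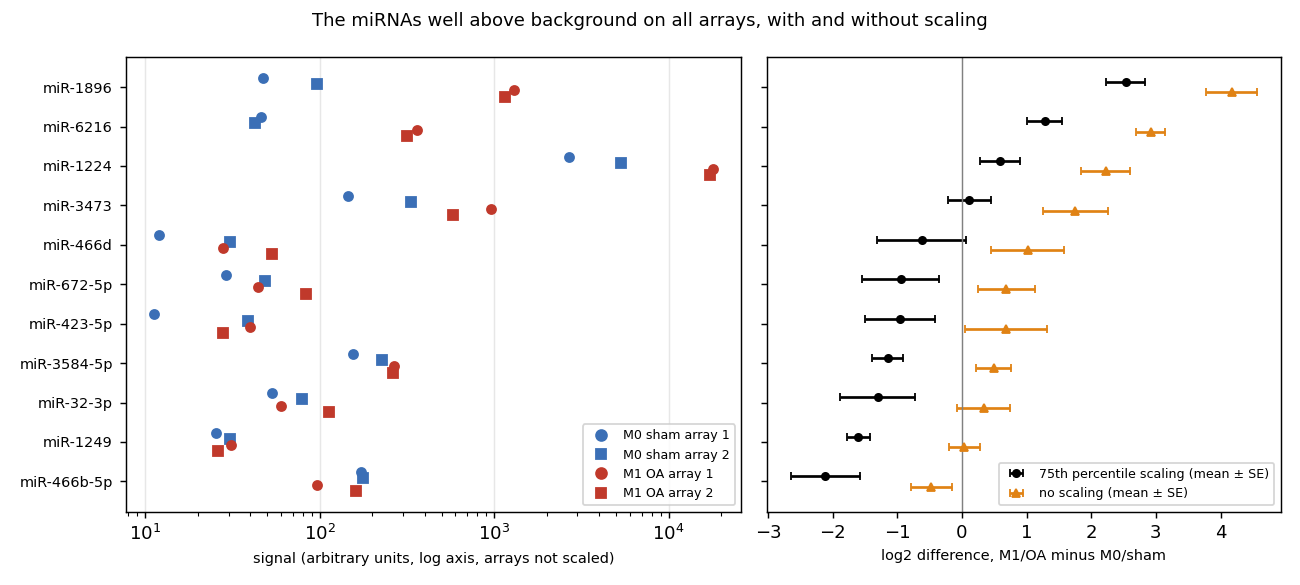
Left, the background-subtracted signals (arbitrary units, log axis, no scaling) of the 11 miRNAs well above background on all 4 arrays, 1 point per array; right, the log2 difference M1_OA minus M0_sham with its SE, after scaling to the 75th percentile (black circles) and without scaling (orange triangles). miR-1896 is higher in M1_OA either way (2.53 and 4.17), while miR-1249 and miR-3584-5p lie below 0 with scaling and above 0 without it.

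Across the 41 miRNAs tested, 22 passed as higher and 4 as lower in M1_OA vesicles (limma, BH-adjusted p under 0.05), and 15 did not pass. Of the 22, 5 had a scaled bound under 1, which does not show a rise. The counts were also 22 and 4 at an unadjusted p under 0.05, and 18 and 4 with an absolute log2 fold change of at least 1 besides. An exact permutation of 2 against 2 arrays cannot give a two-sided p under 0.333. The median log2 difference of the tested miRNAs was 0.62 with the 75th percentile, 0.77 with quantile normalization, 0.84 in the authors' value table, 1.96 without scaling and 2.48 with scaling to the labelling spike-ins. The split of higher and lower calls was 20 and 5 with quantile normalization, 18 and 4 in the authors' table, 32 and 0 without scaling and 34 and 0 with the spike-ins. A 75th percentile over only the 6 all-array miRNAs without CTCC in a probe gave a median of 1.66 and 21 and 0 calls. 14 of the 22 passed as higher under all 6 of these scalings, among them miR-23a-3p, miR-21-5p, miR-146a-5p, miR-34a-5p, miR-155-5p, miR-24-3p, miR-23b-3p, miR-16-5p, miR-188-5p, let-7i-5p and miR-1896. Of these 14, 12 entered the test through M1_OA only, so their rise under any scaling was largely fixed by filter and floor. The counts also rest on how dim signals are treated: a floor at the highest of the arrays' detection limits left 2 of the 41 passing, both higher, miR-23a-3p and miR-21-5p. Normexp background correction with an offset of 50 gave 4 higher and 25 lower. M1_OA-only signals such as those of miR-155-5p (72.4 and 60.3) are of the size of that offset, and normexp without it was not tested.

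The 4 lists with at least 3 tested members were set against the other tested miRNAs with limma's camera at a preset correlation of 0.01, and none passed. The BH-adjusted p was 0.0969 for the LPS and NF-κB list, 0.0969 for the miR-23/24/27 clusters, 0.107 for the M2 list and 0.448 for the myeloid list, all in the direction of M1_OA. At an unadjusted p under 0.05, camera gave 2 lists, the LPS list and the miR-23/24/27 clusters. With an estimated correlation the adjusted p was 0.282, 0.282, 0.282 and 0.619. limma's fry, which asks whether a list's miRNAs move one way and sets them against no other miRNAs, gave BH-adjusted p of 3.85e-04 for the LPS list, 3.85e-04 for the miR-23/24/27 clusters, 4.26e-04 for the M2 list and 0.00211 for the myeloid list. Every tested member of the first 3 lists, and 2 of the 3 myeloid ones, passed the filter through M1_OA only. Their rise under fry was thus largely fixed beforehand and is no separate support.

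Probe positions in the files are on the rat rn4 build. The probe of miR-21-5p (TCAACATCAGTCTGATAAGC) lies on chromosome 10 from 74864520 to 74864538 and that of miR-146a-5p (AACCCATGGAATTCAGTTCT) on chromosome 10 from 28476387 to 28476405. The probe of miR-23a-3p lies on chromosome 19 from 25638793 to 25638809, that of miR-27a-3p on the same chromosome from 25638638 to 25638653, and that of miR-34a-5p (ACAACCAGCTAAGACACTGC) on chromosome 5 from 167187919 to 167187937. Of the 41 tested miRNAs, 28 have a position in the files and 13, miR-155-5p among them, have none there; gene structure around these sites was not analysed here.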

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

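The control features of the arrays were examined after the data had been seen; of them, only the labelling spike-ins dmr_285 and dmr_31a enter a comparison above, as a scaling. Of 22 control features, 7 were well above background on both M1_OA arrays and had median signals there above both M0_sham arrays. Medians before scaling were 19.9-fold higher in M1_OA for hur_2 (29492 and 33754 against 1905 and 1320), 9.01-fold for hur_6, 3.94-fold for hur_1 and 1.86-fold for hur_4. They were 2.59-fold higher for mr_1, 1.41-fold for dmr_3 and 1.34-fold for SCorner3. The feature NegativeControl, not well above background, also had higher medians in M1_OA (10.3 and 6.12 against 3.71 and 3.92). The labelling spike-ins and dmr_6 had lower medians on both M1_OA arrays. What the hur and mr features bind is not given in the sources used here.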

How the results depend on the processing

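Scaling to the spike-ins, the higher floor and the percentile without CTCC-holding probes were chosen after the data were seen. Signals near background limit every count. Testing 11 miRNAs well above background on all 4 arrays, which removes all those measured in 1 group, gave 3 changed (1 higher, 2 lower). Testing all 758, most at the floor, gave 2 (2 higher, 0 lower). These were miR-22-3p and miR-23b-3p (limma, BH-adjusted p = 0.0072 and 0.013). The higher floor gave 2 (2 higher, 0 lower), and these were other miRNAs. Both lost their call with all 758 tested (limma, BH-adjusted p = 0.0956 each). With the higher floor miR-1896 kept its log2 difference of 2.53 and lost its call. Normexp with its offset of 50 gave 4 higher and 25 lower, and how much of this comes from the offset was not tested. Scaling to the spike-ins gave 34 higher. Lower calls numbered 0 without scaling, with the spike-ins and with the percentile without CTCC, 7 with Feature Extraction's gene detection call and 2 in an unmoderated fit at unadjusted p. That detection call left 3 miRNAs in M0_sham only. Where no cause is given, the cause was not tested.

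With normexp and its offset of 50, log2 differences reversed for miR-483-5p (-0.28), miR-34a-5p (-0.18), miR-188-5p (-0.43), miR-155-5p (-0.42), miR-24-3p (-0.37), miR-27a-3p (-0.79), miR-16-5p (-0.67), let-7i-5p (-0.60), let-7b-5p (-0.83), miR-23b-3p (-0.51) and miR-29a-3p (-0.85). Without scaling they reversed for miR-1249 (0.035), miR-3584-5p (0.49), miR-32-3p (0.33), miR-423-5p (0.68), miR-672-5p (0.69), miR-223-3p (1.38) and miR-92a-3p (0.88). With the spike-ins they reversed for miR-466b-5p (0.048), miR-1249 (0.56), miR-3584-5p (1.01), miR-32-3p (0.86), miR-423-5p (1.20), miR-672-5p (1.21), miR-296-5p (0.097), miR-223-3p (1.91) and miR-92a-3p (1.28). Among these, miR-1249 and miR-3584-5p, which fell in the main fit, passed as higher (limma, BH-adjusted p = 0.0122 and 0.00827). With the percentile without CTCC they reversed for miR-3584-5p (0.094), miR-423-5p (0.28), miR-672-5p (0.29), miR-223-3p (0.99) and miR-92a-3p (0.30). miR-1224 reversed in the authors' table (-0.062), miR-223-3p without M0_sham replicate 1 (0.40; range with replicates left out -0.45 to 0.40) and let-7b-5p without M1_OA replicate 2 (-0.034; range -0.034 to 1.07). Of the values of named miRNAs under the alternatives, 368 kept their side of the threshold without reversing, 3 of them at a difference of 0 (miR-1224 with quantile normalization, which sets the brightest miRNA alike on all arrays, miR-92a-3p and let-7b-5p with the higher floor), 78 lost the call, 5 of them at 0, 22 gained one and 35 reversed.

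With 1 replicate left out, the lone array is assumed to vary like the other group. Without an M1_OA array the spread is thus that of M0_sham alone. In the main fit, 16 tested miRNAs had both M0_sham values at the floor and so no spread there. Their calls are then kept largely by the floor. Counts of calls with 1 replicate left out therefore show no stability and are not given. The detection counts were 25 to 29 miRNAs in M1_OA only and 1 to 8 in M0_sham only (8 without M0_sham replicate 2). Camera's BH-adjusted p ranged from 0.0788 to 0.215 for the LPS list, 0.0815 to 0.225 for M2, 0.198 to 0.684 for myeloid and 0.0788 to 0.215 for miR-23/24/27. Fry gave 3.85e-04, 4.26e-04, 0.00211 and 3.85e-04 for them in that order; over all alternatives the highest were 0.287, 0.287, 0.764 and 0.287. Same-numbered arrays deviated together with r = 0.31 over 2 pairs, too few to pair them. The replicate block gave 19 higher calls in place of 22, and 7 lower calls in place of 4, with miR-32-3p, miR-423-5p and miR-672-5p added to the lower ones. It moved the LPS list past the threshold (camera, BH-adjusted p = 0.0478), with no other list moved past it. The 75th percentile over all miRNAs gave no value, being at or below 0; slide could not be a block, the motif test was not run, and no list kept 3 members well above background on all 4 arrays.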

Other observations

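Beyond the miRNAs of the rule, further ones chosen after their values were seen rose in M1_OA vesicles. miR-22-3p, an miRNA of many tissues, was well above background in M1_OA only (87.9 and 59.1, before scaling) and at least 1.61-fold higher with scaling (limma, BH-adjusted p = 0.00104) and 5.00-fold without (limma, BH-adjusted p = 3.80e-04). miR-134-5p was also measured in M1_OA only, at least 1.25-fold higher with scaling (limma, BH-adjusted p = 0.00392) and 3.90-fold without (limma, BH-adjusted p = 2.89e-04), a call that ended in the authors' table (log2 difference 3.79 against 2.01; limma, BH-adjusted p = 0.0527) and without a filter (2.01; limma, BH-adjusted p = 0.337). With normexp the log2 differences of miR-22-3p and miR-134-5p reversed (-0.36 and -0.46), and with the higher floor neither passed (limma, BH-adjusted p = 0.687 and 1). let-7d-5p and miR-30d-5p were well above background on M1_OA replicate 1 alone, and miR-206-3p and miR-212-3p on M1_OA replicate 2 alone. miR-466b-3p was well above background on M0_sham replicate 1 alone (34.1), with signals of -18.1 and -24.6 on the M1_OA arrays.

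The tests on the number of miRNAs well above background were chosen after the result was seen: more miRNAs were well above background in M1_OA (42 and 45) than in M0_sham vesicles (23 and 13). One gain common to all features, as from brighter labelling or scanning of the M1_OA arrays, is argued against by the labelling spike-ins, which lay lower there by a mean log2 difference of -0.529 (highest of the array pairs -0.215). Other control features well above background on all 4 arrays went both ways (dmr_6 1.33-fold lower in M1_OA; SCorner3 1.34-fold, dmr_3 1.41-fold, hur_4 1.86-fold, mr_1 2.59-fold, hur_1 3.94-fold, hur_6 9.01-fold and hur_2 19.9-fold higher), so a technical difference that varies between features stays open. For one common factor, as from a larger small RNA input, the all-array miRNAs served as reference. Of the 19 M1_OA-only miRNAs without CTCC in a probe, 7 had lower bounds without scaling above 4.46-fold. That limit is the highest log2 difference plus 2 SE among the 6 all-array miRNAs without CTCC, a split made after CTCC was noticed. Over all 11 the limit is 31.2-fold, set by miR-1896, with 0 of the 24 M1_OA-only miRNAs above it. The 11 themselves moved apart (4.17 ± 0.40 (SE) for miR-1896 against -0.47 ± 0.32 for miR-466b-5p), which one factor alone does not give. Binding to the probes, taken up below, may add to these signals and need not follow input. The values therefore cannot exclude a larger input acting together with it. Scan session stays open, since 0 of the 2 sessions held both groups, and so do surgery, polarisation and ATP, which these arrays do not separate and which were not tested apart.

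The 11 miRNAs measured on all 4 arrays did not change alike: without scaling, the mean log2 difference was 2.31 for the 5 with CTCC in a probe, the complement of GGAG, and 0.38 for the 6 without (exact permutation p = 0.00866, two-sided, noticed on these same miRNAs). A candidate explanation is loading by GGAG, a motif known for sorting by hnRNPA2B1, and among the miRNAs outside these 11 the median signal difference was 5.34 units higher for the 35 with CTCC in a probe than for the 712 without (permutation p = 1e-05 within 3 strata of probe GC, two-sided, the smallest that 100000 permutations can give). M1_OA was higher for 27 of those 35 (77.1%) and 311 of the 712 (43.7%), although most of these miRNAs lay below background on every array, where a sorted miRNA would not be resolved. A second candidate is binding of purine-rich RNA to pyrimidine-rich probes: among the 712 without CTCC, the difference rose with the C and T share of the probe (Spearman rho 0.341 across miRNAs, which are not independent; one-sided permutation p = 1e-05, again the smallest possible). Probes with CTCC also had a higher median C and T share (55.6% against 47.4%), which the GC strata do not hold fixed. Both may hold, and these arrays do not separate sorting from probe binding. miR-21-5p, miR-23a-3p, miR-146a-5p, miR-155-5p and miR-34a-5p have no CTCC in their probes, but this leaves the second candidate open for them.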
